A study of Drosophila melanogaster with 3 samples.

How the data were processed

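Chromatin immunoprecipitation with sequencing (ChIP-seq) was done on whole Drosophila melanogaster embryos aged 0 to 24 hours that carried a transgene for Otp (orthopedia, a paired-class homeodomain transcription factor) fused to enhanced green fluorescent protein (eGFP). Per the labels, the precipitation used an antibody against GFP, chromatin was sonicated, fragments of 200 to 800 bp were used, and the 3 samples are biological replicates of 1 group. The labels name a separate control experiment as a possible control; its data were not used here. With 1 group, no comparison between conditions was possible. Results were compared between replicates, with random positions, with flanking sequence and with random gene lists.

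Each replicate has 2 peak lists, both made by the authors on the dm6 assembly (Release 6). The first is the list of peaks that passed the irreproducible discovery rate (IDR), a measure of whether a peak keeps its rank in paired lists, and the second is the longer ranked list of all candidate peaks. Peaks carry a signal value per peak in the deposited lists, whose scaling the files do not state, and an IDR score in the deposited lists that is capped at 1000. Every peak of the shorter lists had a score of 830 or more. The ranked lists also hold the deposited −log10 of the IDR. The aligner, the peak caller and their versions are not given in the sources used here, nor is what was paired to compute the IDR of each replicate's lists, parts of 1 replicate or pairs of replicates. In the second case the 3 lists would share libraries. Signal values and scores are the authors' own and served to rank, filter or describe peaks within 1 list and to correlate lists. Of 4 further lists of passing peaks for the whole series, 1 is named conservative by its deposited name and was used as an alternative set; the ranked lists of the whole series were not used here. Peak lists give no read totals, so sequencing depth is unknown and no interval on read counts was computed.

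Peaks of the 3 shorter lists that overlapped by at least 1 bp were merged. A region with a peak of at least 2 replicates was called a consensus region, and its summit was that of the peak with the best percentile rank. Regions were ranked by the mean of their percentile ranks by signal value in the 3 lists, a missing peak counting as the worst rank, so that rank reflects both signal and presence in all 3 lists. Coordinates are 1-based on dm6. Genes, transcripts and transcription start sites (TSSs) came from Ensembl release 115, annotation version 54 of BDGP6, which uses the same coordinates, and sequence came from the Release 6 genome. Transposable elements and pseudogenes were left out, and tests were run on the 6 arms X, 2L, 2R, 3L, 3R and 4. Overlap between replicates was tested against 1000 random placements on the same arm (one-sided). Random placements and matched positions were redrawn in 20 repeats, chosen after the data were seen, to show how far a call rested on 1 draw. Spearman's rho and Pearson's r of log2 signal value were computed across shared regions with 100000 permutations (two-sided). Summits were classed by priority as promoter (within 500 bp of a TSS), 5' UTR, 3' UTR, coding exon, noncoding exon, intron or intergenic, and shares were tested against 1000 random placements (two-sided permutation test). Summits per arm were tested with an exact binomial test against arm length without N. A gene counted as bound if a consensus summit lay in it or within 2000 bp of either end. The bound share of each of 16 gene lists was tested against 10000 random lists of the same size matched on gene length in 20 bins (two-sided permutation test). All 2080 canonical 6-mers and 12 motifs were counted as present or absent in the 100 bp around each summit and in 2 flanking windows of 100 bp centred 500 bp away, with a conditional exact binomial test (two-sided). The share of windows with each motif was tested for a trend over the rank of regions with 100000 permutations, and, chosen after the data were seen, over the regions of all 3 replicates alone. P-values were adjusted with the Benjamini-Hochberg method within each family. The confidence level of intervals is 95% (Wilson for shares of a list, exact for arms), and intervals cover counting error only. Neighbouring genes share summits, and regions and genes are not independent replicates. Values per replicate are given as mean and SD over 3 lists.

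The gene lists, motifs and the rule for naming genes were fixed before the data were examined. So were the tests and alternatives, except those said to be chosen after the data or results were seen. The rule names otp; the 20 best-ranked consensus regions, by the gene that contains the summit or else the gene with the nearest TSS; the 10 genes with most consensus summits; the best-ranked 4 bound members of each gene list past adjusted p 0.05 and at most 2 of the others; the 5 enriched 6-mers with the smallest adjusted p; and all 12 motifs. Names chosen otherwise are said to be so, and 1 item that the rule names is not reported here. Of the list members, 1 of the neuroblast list (Dl) and 3 of the trachea list (dys, sal, tal) matched no single gene in the annotation and were left out, and 3 were matched by an older symbol. Alternatives included stricter peak sets, regions of all 3 replicates, each replicate left out in turn, other overlap rules, promoter widths, gene territories, window sizes and backgrounds.

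The statistics were tested on simulated data before use. For shared peaks, 40% of 2000 simulated peaks were planted as shared and 40.6% were recovered. For gene lists over 13945 genes, 6% of 200 lists of long genes without an effect passed p 0.05 with length matching, against 97.5% without it. For 6-mers at 2000 random positions, 0 of 2080 passed, and a 6-mer planted in 10% of windows ranked 1. For annotation classes at 2000 random summits, 0 of 7 passed. For gene pairs on opposite strands over 13945 genes, 5% of 100 simulated sets without a preference passed p 0.05, and 100% of 20 sets in which genes of pairs were drawn 2 times as often. The computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.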

Results

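The data described where an antibody against GFP recovered chromatin from whole embryos aged 0 to 24 hours that carried Otp-eGFP, in 3 biological replicates of 1 group. Control libraries were not used here, so the peaks were not tested as sites of Otp-eGFP itself. Otp is a homeodomain transcription factor known from the embryonic nervous system and hindgut. Replicates 1, 2 and 3 had 1926, 1813 and 3002 peaks that passed the authors' threshold (2247 ± 656, SD, n = 3), out of 99302, 80933 and 75563 candidate peaks. None of the passing peaks lay on chromosome Y, and 17, 3 and 1 lay outside the 6 arms. Sequencing depth is unknown, because the files hold peaks and not reads.

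The first question was whether the 3 replicates had peaks at the same places. The same region led all 3 lists. It lay at X 2703744 to 2704023, with its summit at 2703882, 30 bp from a TSS of Ugalt (FBgn0024994), which encodes a UDP-galactose transporter. The region at 3L 19590492 to 19590731, 95 bp from a TSS of CG14100 (FBgn0036889), was second in every list. A region in an intron of ph-p (FBgn0004861; X 2137220 to 2137481), a Polycomb group gene, ranked 3, 6 and 3. On average 64.1% ± 13.1 (SD, n = 6 ordered pairs) of the peaks of a replicate overlapped a peak of another. The share ran from 48.8% of the peaks of replicate 3 found in replicate 2 (95% interval 47.0 to 50.6) to the 1450 of 1813 peaks of replicate 2 found in replicate 3 (78.1 to 81.8). Random placement gave 0.866% on average, and each of the 6 shares was above all 1000 placements (one-sided permutation p = 0.001, the smallest they can give). Across shared regions, Spearman's rho of the signal values was 0.748 for replicates 1 and 2 (1193 regions), 0.732 for 1 and 3 (1460 regions) and 0.768 for 2 and 3 (1429 regions). Pearson's r of log2 values was 0.846, 0.829 and 0.851. Each of the 3 pairs had a permutation p of 1e-05 for both measures, before and after adjustment, the smallest that 100000 permutations can give. These correlations are across regions, which are not independent replicates. Whether each replicate's list was made from that replicate alone is not given in the sources used here; if replicates were paired to make the lists, the lists share libraries, and the overlap and correlations are not those of independent replicates.

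Merging gave 3591 regions, of which 1111 had a peak in all 3 replicates, 752 in 2 and 1728 in 1. Replicate 3 alone accounted for 1118 of the regions seen once. The 1863 regions of at least 2 replicates formed the consensus, and 1861 of them lay on the arms. Of the 20 peaks with the highest signal value in each replicate's own list, all 20 overlapped a peak of both other lists, in each of the 3 replicates. Regions were ranked by their mean rank over the 3 lists, with a missing peak counted as the worst rank, so the best-ranked regions have a peak in every replicate by construction. Of the 20 best-ranked regions, 14 were promoters. Beside those of Ugalt and CG14100, promoter summits lay at px (FBgn0003175; 2R 22514301), PNPase (FBgn0039846; 3R 31404647), which encodes a polynucleotide phosphorylase, CG1888 (2R 9547176), Tcs5 (3L 5139503), CG7601 (3R 29736847) and CenG1A (2L 13835473). The other promoter summits were those of Art3 (3R 15229515), an arginine methyltransferase gene, CG18549 (3R 12449170), mRpL41 (2R 15217757), a mitochondrial ribosomal protein gene, lncRNA:CR31044 (3R 29214443), Chro (3L 22878896) and CG5611 (3R 27636171). Intronic summits were found in CG11050 (2L 6612724) and Tlk (X 3742226), a kinase gene, as well as in ph-p. A pair of summits was intergenic, 894 bp from a TSS of lncRNA:CR45643 (3R 16222501) and 11914 bp from a TSS of CG13323 (2R 13035342). The remaining region of the 20 lay in otp itself. The number of consensus regions depended on the rule: 1111 were found in all 3 replicates, and the authors' conservative list gave 3663. Requiring a peak in both other replicates, 1193 remained when replicate 3 was left out, and 1460 and 1429 shared regions were found with replicates 2 and 1 left out.

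The next question was where the peaks lay relative to genes. Promoters held 862 of the 1861 consensus summits, or 46.3%, against 13.5% of random positions, a 3.44-fold excess. The share was 46.3% ± 1.06 (SD, n = 3) over the single replicates. Coding exons were nearly empty, with 6 summits (0.322% against 13.1%). Summits were also fewer than at random in 3' UTRs (0.645% against 5.08%) and between genes (15.3% against 27.5%). Each of these 4 classes had an adjusted permutation p of 0.0035, from p = 0.002, the smallest that 1000 placements can give. Introns held 662 summits, 35.6% against 39.3% (adjusted permutation p = 0.0056). The 5' UTRs outside promoters held 0.591% against 0.776% (adjusted permutation p = 0.464), and were lower when promoters were taken as 1000 bp (0.238-fold, adjusted permutation p = 0.0233). Noncoding exons held 1.24% against 0.756% (adjusted permutation p = 0.0233), but this passed in only 12 of 20 repeats of the random placements (0.0256 to 0.0699) and under 1 of 10 alternative settings. The intron difference did not pass when promoters were taken as 250 bp (adjusted permutation p = 0.691) or when summits were compared with candidate peaks outside the shorter lists (adjusted permutation p = 0.22). The median distance from a consensus summit to the nearest TSS was 600 bp.

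**Figure D1:**
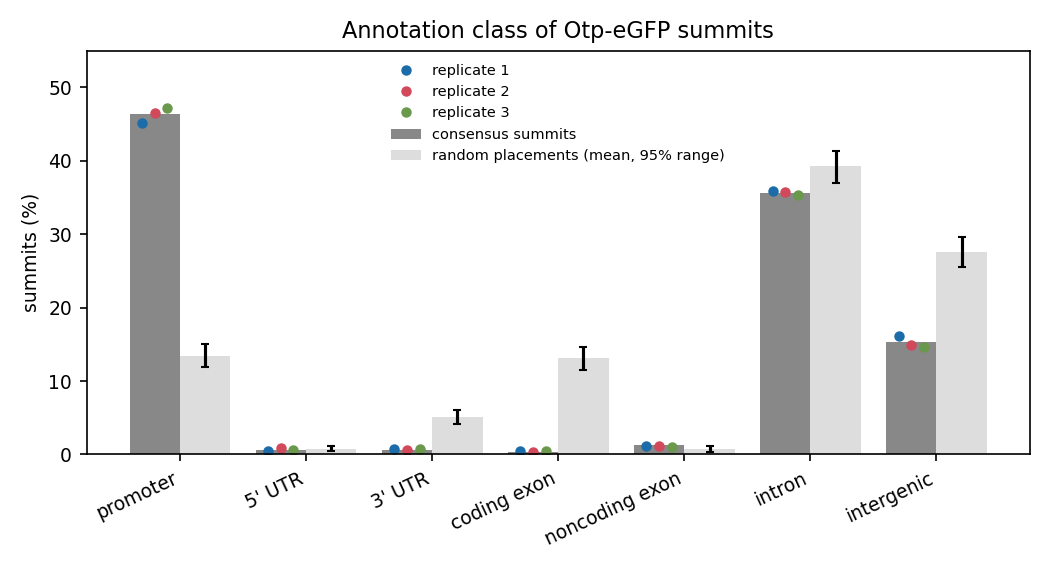
Share of summits in percent (y axis) by annotation class (x axis); dark bars are the 1861 consensus summits, points are the 3 replicates' own lists, and light bars are the mean of 1000 random placements with their 95% range. Promoters stand at 46.3% against 13.5%, and coding exons at 0.322% against 13.1%.

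By chromosome arm, the 4th chromosome carried 1 consensus summit, 0.0537% of summits for 0.996% of the sequence (exact binomial test, adjusted p = 1.7e-06). Arm 2L carried 381 summits, 1.16 times its share of the sequence, and 3R carried 389, 0.872 times its share (exact binomial test, adjusted p = 0.0036 for both). The difference on 3R depended on peaks absent from the shorter lists. Of the candidate peaks whose score passed but which were left out, 34 of 82, 39 of 74 and 68 of 113 lay on 3R in replicates 1, 2 and 3. With these put back, 3R carried 430 of 1928 summits and did not pass (0.930 times, exact adjusted p = 0.176). The shares of 2L and 3R in the single replicates were 19.9% ± 0.946 and 21.8% ± 0.202 (SD, n = 3). Arms X, 2R and 3L carried 335, 353 and 402 summits, 1.02, 1.00 and 1.03 times their shares (exact binomial test, adjusted p = 0.751, 0.953 and 0.741). The difference on 2L did not pass when arms were compared by their number of TSSs (1.05 times, exact adjusted p = 0.279), nor that on 3R with the authors' conservative list (0.953 times, exact adjusted p = 0.234). By number of TSSs, 3L was higher (1.12 times, exact adjusted p = 0.0249), and in regions of all 3 replicates X was higher (1.15 times, exact adjusted p = 0.0367).

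Another question was which genes lay at the peaks. Of 13945 protein-coding genes, 2319 (16.6%) had a consensus summit within the gene or 2 kb of it. Ribosomal protein genes stood out, with 55 of 86 bound (64.0%) against 12.2% for random lists of like gene length, a 5.23-fold excess (permutation p = 2e-04, the smallest that 10000 random lists can give, adjusted p = 0.0011). The bound share was 63.6% ± 8.57 (SD, n = 3) over single replicates and passed under each of 12 alternative settings. With only 1 kb around each TSS counted, the excess was 8.6-fold (adjusted permutation p = 0.0016). The best-ranked summit was nearest to a TSS of the gene itself for 47 of the 55 and to that of another gene for 8. Among the best-ranked sites within 2 kb of these genes were those at RpL7 (FBgn0005593), RpL3 (FBgn0020910) and RpS27 (FBgn0039300), ranked 72, 80 and 87 among the consensus regions. RpL7 (2L 10201004 to 10202321, plus strand) had its summit at 10201022 and RpS27 (3R 25245955 to 25247514, minus strand) at 25247521, both at the gene's own 5' end. The summit at RpL3 (3R 11226666) lay beyond the 3' end of the gene and in the promoter of another.

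The cuticle, chemosensory and neurotransmission lists were bound less often than random lists. Among cuticle protein genes, 2 of 118 were bound (1.69% against 11.4%), namely Cpr76Ba and Cpr31A. Among chemosensory genes (odorant, gustatory and ionotropic receptors and odorant-binding proteins), 8 of 230 were bound (3.48% against 13.5%), the best-ranked being Ir68b, Or85f, Or88a and Obp99b. For 6 of the 8 the best-ranked summit was nearest to a TSS of another gene: that of Ir68b lay 27 bp and that of Or88a 372 bp from a neighbour's TSS, and that of Or85f lay 48 bp from the TSS of a gene of the ribosomal protein list and was counted there too. The same held for 1 of the 2 cuticle genes, Cpr31A. Both lists had the same smallest permutation p of 2e-04, adjusted p = 0.0011, and the shares over single replicates were 2.26% ± 0.979 and 4.35% ± 0.753 (SD, n = 3). Of 38 neurotransmission genes, 3 were bound (7.89% against 31.4%, adjusted permutation p = 0.0048). These were elav, which encodes a neuronal RNA-binding protein, nAChRalpha5 and Nmdar1, both receptor genes, whose summits were nearest to a TSS of another gene (180 and 27 bp). When only the gene itself counted, none of the 3 lists passed (adjusted permutation p = 0.42, 0.117 and 0.128 for cuticle, chemosensory and neurotransmission genes). The neurotransmission list also missed the threshold with 5 kb on each side (adjusted permutation p = 0.108), with 1 kb around each TSS (0.0872) and without length matching (0.259).

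None of the other 12 lists passed after adjustment. The PRD-class homeobox genes, the class of otp, had 2 of 27 members bound, otp and unc-4 (7.41% against 26.4%, adjusted permutation p = 0.0794). In the HOX cluster list 4 of 12 were bound (33.3% against 28.5%), among them bcd and Antp. In the list of other homeobox genes 14 of 52 were bound (26.9% against 27.1%), among them NK7.1 and tup. Early patterning genes had 11 of 42 bound (26.2% against 21.5%), including ush and nkd. Neuroblast and proneural genes had 9 of 28 (32.1% against 19.6%), including brat and E(spl)m8-HLH. Of the lists for tissues, hindgut genes had 8 of 21 bound (38.1% against 22.9%), with bowl and fkh the best-ranked. Glia genes had 6 of 16 (37.5% against 24.3%, moody and pnt), muscle genes 9 of 25 (36% against 28.0%, Mef2 and sls) and trachea genes 4 of 15 (26.7% against 29.5%, rib and pio). Axon guidance and adhesion genes had 15 of 43 bound (34.9% against 35.9%, kirre and Sema1a). Neuropeptide and neuroendocrine genes had 3 of 33 (9.09% against 16.6%, amon and ITP) and cell cycle and replication genes 8 of 27 (29.6% against 17.0%, CycB and fzr). Apart from the PRD class, the smallest adjusted permutation p of these lists was 0.315. CycB, a mitotic cyclin gene, had a region ranked 47 within 2 kb. In each of these 12 lists, at least 1 bound gene had its best-ranked summit nearest to a TSS of another gene. Of the 14 bound other homeobox genes, the nearest TSS was the gene's own for 8 and another's for 6. Of the 8 bound cell cycle genes these numbers were 3 and 5. The best-ranked summits of tup, E(spl)m8-HLH, Mef2 and fzr lay 113, 131, 119 and 333 bp from a TSS of another gene.

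**Figure D2:**
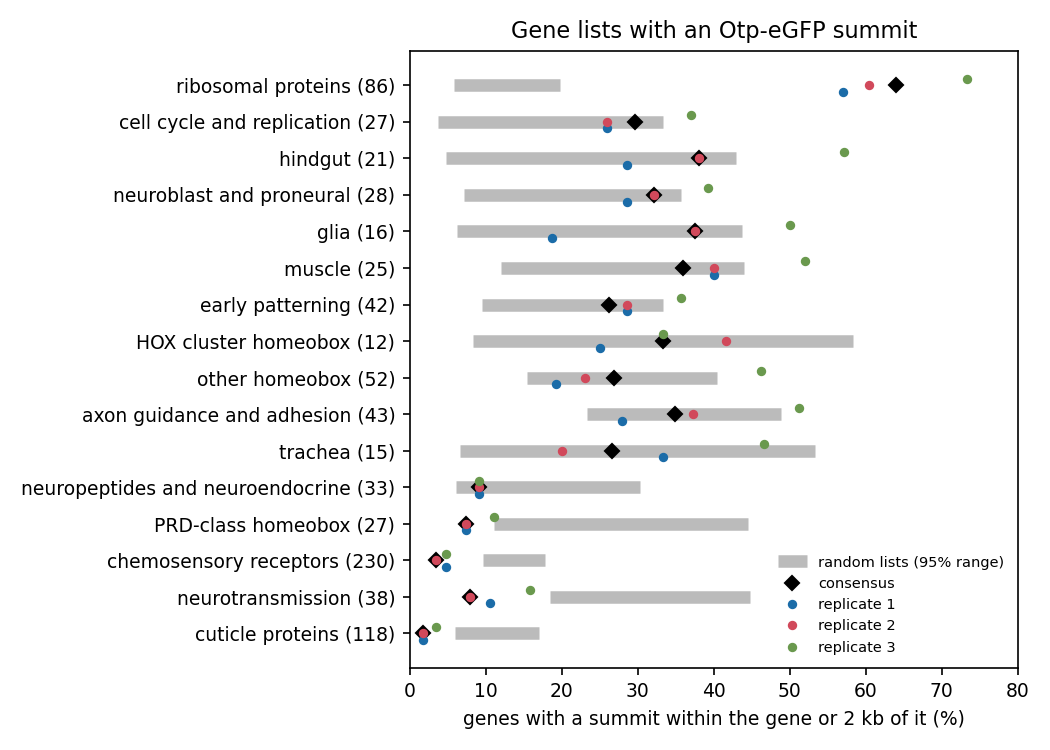
Share of the genes in each of 16 lists (y axis, number of genes in brackets) with a summit in the gene or within 2 kb, in percent (x axis); diamonds are consensus regions, points the 3 replicates, and bars the 95% range of 10000 random lists matched on gene length. Ribosomal protein genes lie at 64.0%, right of their range, and cuticle protein genes at 1.69%, left of theirs.

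The genes with the most consensus summits were CG1677 (FBgn0029941) and kirre (FBgn0028369), with 8 each, and sbb (FBgn0285917), with 7. Each of CHES-1-like, Eip75B, mew and ush had 6. Eip75B encodes a nuclear receptor and mew an integrin subunit. A further 12 genes tied at 5 for the last places, so all are named: Ptpmeg2, Raf, Rtnl1, apt, dlp, dnc, gukh, otp, px, shn, sick and trio. Of these genes, kirre spans 394 kb, CG1677 spans 125 kb and Rtnl1 spans 16.9 kb.

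A further question was which sequences lay under the summits. Summit windows were rich in A and T: mean GC content was 36.2% at consensus summits, 42.6% in flanks and 42.2% over the 6 arms, and 37.4% ± 1.47 (SD, n = 3) over single replicates. The 5 enriched 6-mers with the smallest adjusted p were AAATAT, TTAAAA, TAAATA, ATTTTA and AATATA. AAATAT was present in 30.4% of summit windows and 16.3% of flanks, with a fold of 1.72 ± 0.104 (SD, n = 3) over replicates and 1.87 in the consensus (exact binomial test, adjusted p = 9.3e-23). The folds of the other 4 were 1.85, 1.85, 1.83 and 1.97, with adjusted p of 1.9e-20, 7.2e-20, 1.7e-18 and 1.7e-18. In all, 306 6-mers were enriched and 477 depleted, and 35 of the 36 made only of A and T were among the enriched. Against positions matched on GC content and distance to a TSS, 56 were enriched (35 to 58 in 20 repeats of the random draw), and none of those 5 passed (exact binomial test, smallest adjusted p = 0.129).

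Among the 12 fixed motifs, 3 were more frequent at summits than in flanks and 1 less frequent. The DRE motif TATCGATA, bound by BEAF-32 and DREF at promoters of broadly expressed genes, was in 34 summit windows (1.83% against 0.349%, 5.23-fold, exact binomial test, adjusted p = 7e-07), with a fold of 3.83 ± 0.354 (SD, n = 3) over replicates. It also passed against matched positions (3.58-fold, exact adjusted p = 7.1e-05), and in each of 20 repeats of that draw (2.52-fold to 4.86-fold). The homeodomain core TAATTA was in 161 windows (8.65% against 6.53%, 1.33-fold, exact adjusted p = 0.0362), with 1.31 ± 0.115 (SD, n = 3) over replicates. Against matched positions its fold was 0.997 (exact adjusted p = 1) and 0.83 to 1.04 in 20 repeats, none of which passed. Over the 10 alternative settings it passed in 4: with flanks 1000 bp away (1.54-fold, exact adjusted p = 3.2e-04), in the authors' conservative list (1.22-fold, 0.0199), without replicate 2 (1.39-fold, 0.016) and with a signal value of at least 20 (1.33-fold, 0.0362). Besides the matched positions, it missed the threshold without replicate 1 (1.21-fold, exact adjusted p = 0.278), without replicate 3 (1.32-fold, 0.0768), in regions of all 3 replicates (1.35-fold, 0.0657), with 200 bp windows (1.19-fold, 0.089) and with the left-out peaks put back (1.27-fold, 0.0626). The promoter motif core GGTCACAC was in 10 windows against 5 of the flanks (4-fold), and the E-box CAGCTG in 70 (0.711-fold), both with an exact adjusted p of 0.0406. Neither passed against matched positions (1.18-fold, exact adjusted p = 0.749, and 1.43-fold, 0.0804) or with the left-out peaks put back (3.33-fold and 0.726-fold, both 0.0626). Over 10 alternative settings, GGTCACAC passed in 7 and CAGCTG in 4.

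The other 8 motifs did not pass against flanks. The folds were 1.04 for TAATTG, 0.864 for TAATCC, 1.64 for the paired-type dimer TAATNNNATTA, 0.86 for GAGAGAG, 0.736 for CAGGTA, 0.604 for CACGTG, 1.22 for CCCTCT and 0.996 for AGATAA. The smallest adjusted p of these 8 was 0.15. Some passed in another set of regions: TAATNNNATTA was higher without replicate 2 (2.17-fold, exact adjusted p = 0.016), with folds of 2.06, 1.09 and 1.28 in replicates 1, 2 and 3. GAGAGAG was lower without replicate 3 (0.508-fold, exact adjusted p = 0.0419) but higher in the authors' conservative list (1.43-fold, 0.0117), and CCCTCT was higher in that list (1.44-fold, 0.0065). Against matched positions GAGAGAG was higher (2.06-fold, exact adjusted p = 0.0157), and this passed in 13 of 20 repeats of the draw; CCCTCT did not (1.54-fold, 0.0578), but passed in 15. Across regions ordered by rank, TAATTA showed no trend (permutation p = 0.721). GAGAGAG was more frequent in regions of lower rank, at 1.07% of the top decile and 3.76% of the bottom decile (permutation p = 0.00136, adjusted p = 0.0163). Only 6 of the 186 regions of the bottom decile had a peak in all 3 replicates, against all 187 of the top decile, and among the 1110 regions of all 3 replicates the trend of GAGAGAG did not pass (0% and 3.6%, adjusted permutation p = 0.388).

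**Figure D3:**
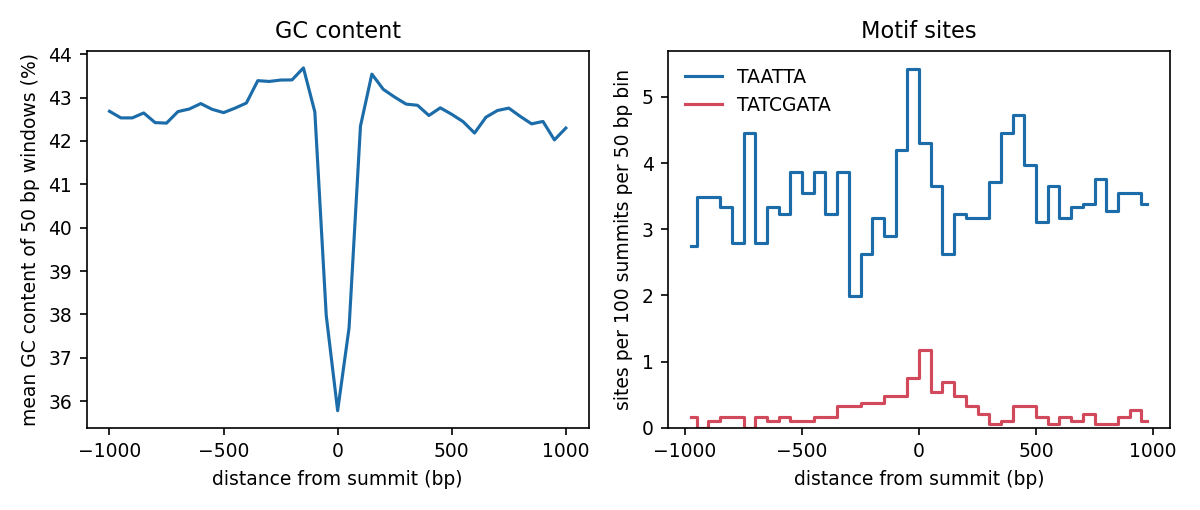
Left, mean GC content in percent of 50 bp windows (y axis) by distance from the consensus summit in bp (x axis). Right, TAATTA and TATCGATA sites per 100 summits in bins of 50 bp (y axis) by the same distance; GC content averages 36.2% in the central 100 bp against 42.6% in the flanks 500 bp away, and TAATTA is present in 8.65% of the central windows against 6.53% of the flanks.

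The last question concerned the tagged gene. The gene otp (FBgn0015524) lies at 2R 20883625 to 20903414 on the minus strand, with the homeobox genes Rx and hbn upstream of it. Its strongest region, at 2R 20884472 to 20884748, was the eleventh consensus region overall and ranked 10, 15 and 13 in the lists of replicates 1, 2 and 3. The summit at 20884601 lay in the last coding exon (20884495 to 20884761 in 8 of the 9 annotated transcripts), 107 bp from the stop codon of those transcripts (20884492 to 20884494). The position of the tag and the stretch of genome carried by the transgene are not given in the sources used here, so a contribution of the transgene itself to this region was not tested. The region held 1 of 6 consensus summits in coding exons; the others lay in Pde1c, l(3)mbn, CG10357, mtd and klar, named here after their values were seen. Introns of otp held 3 further regions, with summits at 20885917, 20888931 and 20898664, and another lay 1319 bp upstream of the gene at 20904733. Within 100 kb of otp there were 10 consensus regions, of which 3 had a peak in all 3 replicates; 5 were found without replicate 2 and 3 without replicate 3. The genes Rx and hbn had 0 consensus regions within the gene or 2 kb of it. In the longer ranked lists, otp held 28, 26 and 25 candidate peaks, and the gene with 100 kb on each side 255, 213 and 202.

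**Figure D4:**
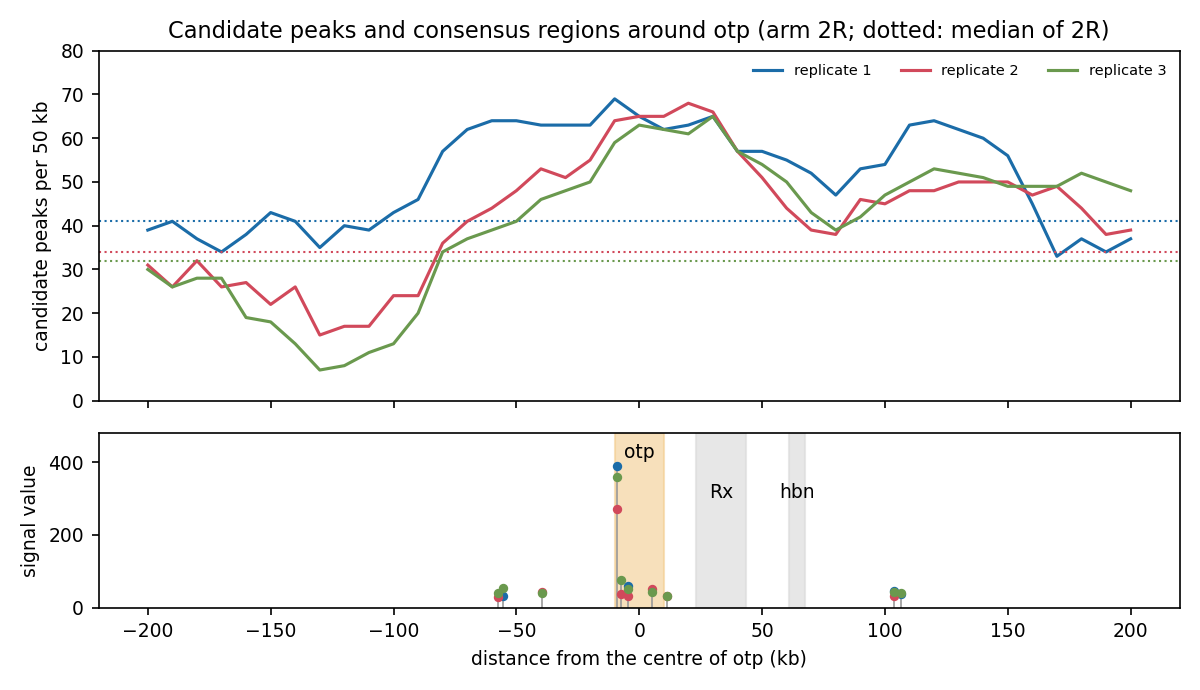
Top, candidate peaks per sliding 50 kb window (y axis) by distance from the centre of otp in kb (x axis), 1 line per replicate, with dotted lines at the median of arm 2R. Bottom, signal value in each replicate's own list (y axis) at the 10 consensus regions within 100 kb, with otp, Rx and hbn shaded; the tallest points, at 388, 272 and 358, are the region in the last coding exon of otp.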

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

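The tests of homeobox genes, of the wider stretch of 2R, of base composition and of the promoter share of candidate peaks and of trends among regions of all 3 replicates, and all repeats of random draws, were chosen after the results were seen.

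Some peaks lay outside what the comparisons used. Replicate 1 had 17 passing peaks outside the 6 arms, above the 3 counts that a count of 0 allows, while replicates 2 and 3 had 3 and 1. The ranked lists also held candidate peaks whose score passed but which are absent from the shorter lists: 82 in replicate 1, 74 in replicate 2 and 113 in replicate 3. Of these, 34, 39 and 68 were on arm 3R, and their median signal values were 46.8, 41.9 and 44.8. With them put back, the lower share of summits on 3R no longer passed (0.930 times). Why they were left out is not given in the sources used here.

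Candidate peaks were dense around otp, with 65, 65 and 63 in the 50 kb centred on the gene against a median of 41, 34 and 32 in windows of arm 2R. Density at homeobox genes in general is argued against, since 100% of 89 other homeobox genes had fewer in each replicate; the highest was the neighbour Rx, whose window overlaps (62, 64 and 62), and apart from Rx 57, 54 and 60. A rich stretch reaching as far as 100 kb to both sides is argued against too, since the windows centred there reached at most percentile 91.1 of windows on 2R. No other windows were tested, and the right one held more than the 2R median in each replicate (54, 45 and 47). In replicate 1, however, the windows centred 60 kb to the left and 120 kb to the right each held 64, nearly as many as otp. The window centred 120 kb to the right held 48 in replicate 2 and 53 in replicate 3, also above the 2R medians of 34 and 32. A broad, patchy or one-sided stretch stays open in all 3 replicates. Extra copies of the locus carried by the transgene may account for the density, since the window at otp lay at percentile 99.1 or above in all 3 replicates, and whether they or the tag gave the strong region 107 bp from the stop codon was not tested; a locally rich stretch or binding of Otp there would give the same density, and no biological explanation was tested.

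The homeodomain core TAATTA was 1.33-fold enriched at summits against flanks. AT-rich base composition of the summit windows may account for this. Against positions matched on GC content and distance to a TSS, the fold was 0.997 with an upper 95% bound of 1.21 (at most 1.26 in 20 repeats of the draw). Both were matched together, so the drop cannot be assigned to base composition alone. Direct binding of the homeodomain at the strongest peaks was tested by rank, and the top decile had TAATTA in 7.49% of windows against 9.68% in the bottom decile (10.8% against 8.11% among regions of all 3 replicates, permutation p for trend = 0.463). The difference of -2.19 percentage points has a 95% interval of -7.87 to 3.49 (permutation p = 0.828, one-sided), so with 187 and 186 windows an excess in strong peaks cannot be told apart from none. Rank also went with base composition, at a mean GC content of 32.2% in the top decile and 39.9% in the bottom decile. An excess could thus have come from base composition alone, and the test could not have pointed to binding. No biological explanation beyond direct binding was tested.

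Consensus summits were 3.44-fold enriched at promoters and frequent at ribosomal protein genes. Candidate peaks outside the shorter lists had 16.4% of summits at promoters, against 13.5% of random positions and 46.3% of consensus summits. A promoter excess of the same size among those candidate peaks is argued against. Those are mostly weak: the median signal value averaged 9.8 over the ranked lists and 49.5 over the shorter lists. Among the 1110 regions of all 3 replicates, promoters were more frequent at higher signal value, in a test chosen after the data were seen. They made up 57.7% of the top decile and 37.8% of the bottom decile (permutation p for trend = 0.00057). Whether strong peaks lie at promoters also without Otp-eGFP was not tested. Open promoter chromatin recovered without the factor may contribute: 2 of the 3 motifs named for it (TATCGATA and GGTCACAC) were enriched at summits, though GGTCACAC, with 10 windows, was not against matched positions or with the left-out peaks put back (3.33-fold, exact adjusted p = 0.0626). The third, GAGAGAG, lay at 0.86-fold against flanks and 2.06-fold against matched positions (exact adjusted p = 0.0157), passing in 13 of 20 repeats. Enrichment of a motif against flanks can follow from the promoter share of summits alone. For TATCGATA this is argued against, since it was 3.58-fold enriched against positions matched on GC content and TSS distance. That enrichment passed (exact adjusted p = 7.1e-05), and did so in each of 20 repeats. Binding of Otp-eGFP at promoters could give motif enrichment too, so the motifs cannot tell recovery without the factor from binding. Control libraries, which would bear on this, were not used here, and no biological explanation was tested.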

How the results depend on the processing

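Matching to candidate peaks of the other replicate, peaks with a signal value of at least 20, the left-out peaks of passing score put back, the alternatives for the otp locus and the repeats of random draws were chosen after seeing the data. Over 75 results and 26 settings, 392 of 485 alternative values with a test kept their direction and their side of the threshold (71 of 83 that answer a comparison and 321 of 402 others), and of 57 without a test, 43 stayed within 1.5 times or 1 SD. A further 69 values were means over the replicates or pairs left after 1 replicate was dropped. These values moved, but by construction they could not change side of the threshold or move by 1 SD, so they were not counted. Overlap between replicates, rank correlation, the promoter excess (2.45-fold to 4.98-fold), the ribosomal protein list (3.33-fold to 16.3-fold) and TATCGATA (3.4-fold to 7.56-fold) did so in every setting run for them. Apart from values fixed by construction, rank correlation was rerun only with candidate peaks matched to consensus regions (mean rho 0.686 against 0.749). The direction of overlap could not change, since a share cannot fall below 0. The number of consensus regions was 1111 in all 3 replicates, 3663 in the conservative list and 1193 to 1460 without 1 replicate, where both others had to share a region, which lowers the count by construction. The regions within 100 kb of otp numbered 3, 18 and 3 to 8 in the same sets. With the gene alone as territory 1 gene list passed, and the folds were 0.352 for neurotransmission and 0 for both chemosensory and cuticle genes, with few genes bound at all by construction. The neurotransmission fold was 0.566 with 5 kb on each side, 0.168 with 1 kb around TSSs and 0.472 without length matching; the cause was not tested. Of results that did not pass, 7 passed in another setting with the direction kept: the neuropeptide list (0.337) and CCCTCT (1.44) in the conservative list, TAATNNNATTA without replicate 2 (2.17), GAGAGAG without replicate 3 (0.508), arm X in regions of all 3 replicates (1.15), arm 3L by number of TSSs (1.12) and 5' UTRs with promoters of 1000 bp (0.238). TAATTA passed with flanks 1000 bp away (1.54-fold) and in the conservative list (1.22-fold), missed the threshold in regions of all 3 replicates (1.35-fold) and with 200 bp windows (1.19-fold), and lay at 1.21 to 1.39 without 1 replicate. With the left-out peaks put back, TAATTA (1.27), CAGCTG (0.726), GGTCACAC (3.33), arm 3R (0.930) and noncoding exons (1.58) missed the threshold, and arm X (0.989), arm 2R (0.982) and AGATAA (1.03) changed direction. The number of motifs past the threshold was 2 with 200 bp windows, with flanks 1000 bp away and against matched positions, 2 to 5 without 1 replicate and 1 with the left-out peaks put back. Against matched positions 56 6-mers were enriched, and the folds of TAATTA (0.997), TAATTG (0.897), GAGAGAG (2.06) and CAGCTG (1.43) changed direction. Which motifs passed there changed with the random draw: over 20 repeats TATCGATA passed in 20, CCCTCT in 15, GAGAGAG in 13, AGATAA in 2 and the paired-type dimer in 1. GAGAGAG also turned in the conservative list (1.43, exact adjusted p = 0.0117). The axon guidance fold turned to 2.11 without length matching (adjusted permutation p = 0.0176), as lists of long genes without an effect did in simulated data. The other changes of direction were in values that passed in neither setting. Without length matching these were other homeobox genes at 1.62 and trachea genes at 1.6. In the conservative list they were HOX cluster genes at 0.984, other homeobox genes at 1.29, trachea genes at 1.18, AGATAA at 1.09 and arm X at 0.955. In regions of all 3 replicates they were HOX cluster genes at 0.432, cell cycle genes at 0.975, CCCTCT at 0.892 and arm 2R at 0.919. With the gene alone, axon guidance lay at 1.09 and trachea genes at 1.32, and with 1 kb around TSSs HOX cluster genes lay at 0.611 and muscle genes at 0.562. With 200 bp windows TAATTG lay at 0.962, GAGAGAG at 1.2, CAGGTA at 1.03, CACGTG at 1 and AGATAA at 1.05; with flanks 1000 bp away CCCTCT lay at 0.952 and AGATAA at 1.02, and with a signal value of at least 20 AGATAA lay at 1. By number of TSSs arm 2R lay at 0.914. Without 1 replicate the ranges were 0.91 to 1.03 for arm 2R, 0.993 to 1.07 for arm 3L, 0.711 to 1.06 for HOX cluster genes, 0.771 to 1.03 for other homeobox genes, 0.868 to 1.02 for axon guidance, 0.938 to 1.94 for glia genes, 0.618 to 1.09 for trachea genes, 0.827 to 1.01 for TAATCC, 0.952 to 1.01 for CCCTCT and 0.96 to 1.05 for AGATAA. For the changes of direction the cause was not tested. Read depth is unknown, so its effect on the number of peaks could not be assessed.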

Other observations

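The tests of short sequences against all flanks and against matched positions were fixed before the data were examined. The sequences named, the repeats of random draws and all other tests in this part were chosen after the data were seen. Consensus summits lay at gene pairs that start close together on opposite strands more often than sharing of summits within pairs gave. Of 4648 protein-coding genes whose 5' end lay within 1000 bp of a divergent 5' end, 505 (10.9%) had a consensus summit within 500 bp, against 378 of 9297 other genes (4.07%). A summit can count for both genes of a pair, so summits given to genes drawn at random, at the distances seen at other genes, already gave a ratio of 1.76 (95% range 1.48 to 2.07). The ratio was 2.67 in the consensus (one-sided permutation p = 1e-04, the smallest that 10000 draws can give), 1.52 times that value. Over single replicates it was 2.57 ± 0.345, or 1.48 ± 0.181 times the value by chance (SD, n = 3). The draw took no account of how active genes are, which peak lists do not measure. A difference in activity between genes of pairs and other genes was therefore not tested. By gene class, 7.6% of protein-coding genes had a consensus summit within 500 bp of any TSS. The share was 2.76% of 290 tRNA genes (Wilson 95% interval 1.4 to 5.35) and 3.72% of 269 snoRNA genes (2.03 to 6.71). It was 2.73% of 3261 ncRNA genes (2.22 to 3.35) and 0% of 99 rRNA genes (0 to 3.74). A gene with more TSSs has more chances to count. The shares were not matched for this, and the difference between classes was not tested.

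Regions of better rank, which reflects both signal value and a peak in all 3 replicates, were more often promoters and had lower GC content. Promoters made up 59.9% of the top decile and 43.0% of the bottom decile (permutation p for trend = 0.00073), and mean GC content was 32.2% and 39.9% (permutation p = 1e-05, the smallest that the permutations can give). Among the 1110 regions of all 3 replicates alone, where only signal value sets the rank, promoters made up 57.7% of the top decile and 37.8% of the bottom decile (permutation p for trend = 0.00057), and mean GC content was 31.7% and 38.5% (permutation p = 1e-05).

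Related 6-mers stood out from the AT-rich background in 2 families. ACAGTG was in 7.79% of summit windows, 4.14% of flanks and 3.57% of matched positions (exact binomial test, adjusted p = 1.2e-07 against matched positions; 1.87-fold to 2.69-fold in 20 repeats of the draw), with a fold against flanks of 1.99 ± 0.283 (SD, n = 3) over replicates. ACTGTG and ACACTG were 2.09-fold and 1.87-fold more frequent than at matched positions (passing in 19 and 20 of 20 repeats). C-rich 6-mers were also more frequent than at matched positions, but did not pass against flanks. CCCCCC was 3.92-fold and GCCCCC 3.55-fold more frequent (exact binomial test, adjusted p = 3.8e-06 for both; 2.04-fold to 4.08-fold and 1.86-fold to 2.75-fold in 20 repeats), ACCCCC 2.52-fold and AGGGGG 2.41-fold (exact adjusted p = 1.9e-04 and 1.6e-04), and each passed in all 20 repeats. Against flanks these 4 lay at 1.01, 1.01, 1.26 and 1.08, and none passed (smallest exact adjusted p = 0.257). CCAGGA was nearly absent, with 0.376% of summit windows against 3.52% of flanks, which are richer in GC. At matched positions it was in 3.33% (0.113-fold, exact adjusted p = 2.3e-11), and this passed in each of 20 repeats. These 6-mers were picked after their values were seen. Of 6 of these and related 6-mers tested outside coding sequence, 5 passed. The share of CCAGGA was 0.38% against 1.81% of flanks (0.21-fold, against 0.107-fold over all flanks; Fisher's exact test, adjusted p = 1.2e-05), and that of AAGGAC 0.977% against 2.34% (0.417-fold, adjusted p = 6.2e-04). CAGGAC, at 0.412-fold over all flanks, did not pass there (0.648-fold, exact adjusted p = 0.185). ACAGTG lay at 7.81% against 4.19% (exact adjusted p = 1.2e-06), and ACTGTG and ACACTG at 1.62-fold and 1.59-fold (exact adjusted p = 2.7e-04 and 3.2e-04). No factor was assigned to these sequences.

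Most passing peaks of a replicate overlapped a candidate peak of each other replicate. On average 96.2% ± 2.76 (SD, n = 6 ordered pairs) overlapped a candidate peak of another replicate, against 31.2% at random positions and 64.1% for passing peaks. CG3434, a gene of 1.43 kb, had 4 consensus summits in its territory, and was chosen after its values were seen.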
